A study of Mus musculus with 6 samples.

How the data were processed

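Total RNA was sequenced from satellite cells of mouse hind limb, freshly isolated and sorted, in 3 libraries from homozygous Lmna mutants and 3 from wild-type mice at postnatal day 19. Libraries were made with a stranded total RNA kit with ribosomal RNA removal, per the labels' protocols. The authors deposited raw read counts per Ensembl gene, 1 file per library, ending with summary lines for reads assigned to no gene. Trimmomatic 0.32, STAR 2.5.2b, HTSeq 0.6.1 and build mm10 are named per the submitters' processing notes. Their roles, the strand setting and the annotation release are not given in the sources used here. Each library was placed in its group from its title.

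The files hold 39059 genes, of which 38861 matched an identifier in GENCODE release M21 on GRCm38, the same assembly as mm10, which supplied symbols, biotypes and positions. Summary lines were left out of library totals and tests. They made up 45 to 49.8% of all reads in a file. Reads outside annotated genes were 22.8 to 29.2% and reads with more than 1 alignment 19.7 to 24% of all reads in a file. Gene totals ran from 6613636 to 9552751 reads. No pair of libraries within a genotype agreed within sampling noise, as 1 library deposited under 2 names would (chi-square of 9.34 to 25.6 per gene). This does not show that they came from separate animals.

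Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), normalised with TMM factors, and compared between genotypes with the quasi-likelihood test without covariates. P-values were adjusted by the Benjamini-Hochberg method over 14099 genes, with a threshold of 0.05. The common biological coefficient of variation was 0.162. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Expression is given as CPM on TMM-scaled totals, as mean ± SD over 3 libraries, and log2 fold changes are homozygous minus wild type. Gm42418 is given as CPM on unscaled gene totals. For genes with 0 reads in a group, a lower bound was computed against 3 reads over the group. For genes with 1 to 3 reads, the ratio of pooled counts is given with an exact 95% interval. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

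23 gene lists and 9 cell type marker lists were fixed from textbook knowledge before the data were examined, as were the test, the alternatives and the rule for named genes. Lists with at least 5 measured members, 31 in all, were tested with limma 3.58.1 by camera on voom values with a preset correlation between genes of 0.01. Beside it stood camera with an estimated correlation and fry, a self-contained test of whether a list moves on balance in a given direction. Adjusted p-values of lists are over the 31 lists. 15 lists passed with the preset correlation, 0 with an estimated correlation and 4 with fry. Member counts are given over all genes tested and adjusted over the list alone. Shares of counts were compared by exact two-sided permutation tests over the 20 assignments of 6 libraries, which cannot give a p below 0.1.

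Named genes are (1) Lmna, Pax7, Myf5, Myod1, Myog, Cdkn2a, Cdkn1a, Ezh2 and Mki67, (2) the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM, values that do not overlap between genotypes and a symbol that is not a predicted-gene name, and (3) per list, up to 4 called members with the smallest p, or the 2 most abundant where none was called. Other genes, such as Acta2, Rn7sk, H19, Igf2 and lone members that moved against their list, were chosen after their values were seen. Values of some single genes that the rule or a count of 5 or fewer would name are not reported here. Of 129 entries under this rule, 36 are genes whose exons overlap those of another gene, among them Abcc9, Casq1, Cbx7, Col15a1, Ezh2, Map2, Plin4, Ryr1, Sun2, Uqcrb and Vcam1 on the opposite strand and Col3a1 on the same strand. Their counts are uncertain to that extent.

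On counts simulated from the real means and library sizes, with 200 of 13876 genes changed, the gene test recovered 65% of genes changed 2-fold and 93% of those changed 4-fold, with 5.95% false calls among the genes called. A p53 target list raised 1.5-fold was called, with 1 other list of the 31. Genes were simulated independently of each other, so this does not check the list test on genes that vary together. The alternatives were DESeq2 size factors in edgeR, library totals only, the DESeq2 1.42.0 Wald test, voom with sample quality weights, no filter on low counts, a filter of 1 CPM in 3 samples, the replicate number as a block, a test against a fold change of 1.5, counts thinned to 6613636 reads, omission of mitochondrial, ribosomal, histone and haemoglobin genes, and omission of each library. Presence of Y-linked reads as a covariate and omission of the 2 libraries high in Gm42418 were added after seeing the data.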

Results

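RNA was sequenced from satellite cells, the stem cells of skeletal muscle, which had been sorted by flow cytometry from the hind limbs of C57BL/6J mice at postnatal day 19. 3 libraries came from mice homozygous for a deletion of exons 8 to 11 of Lmna, the gene for the nuclear lamins A and C, and 3 from wild-type mice. Reads assigned to genes numbered 7350574, 9552751 and 7234298 in homozygous replicates 1, 2 and 3, and 8426578, 6613636 and 7936471 in wild-type replicates 1, 2 and 3. The labels speak of 3 mice per condition without tying each library to its own animal, so the p-values measure only the spread between these samples, which may in part be technical. Reads from 4 Y-linked genes numbered 4498 in homozygous replicate 2, 3074 in wild-type replicate 2 and 4831 in wild-type replicate 3, against at most 3 in each of the other libraries, so both genotypes held libraries with and without a Y chromosome. Acta2, the smooth muscle actin, a transcript of other cell types, was abundant in both genotypes and stood at 4080 ± 154 CPM (gene counts scaled to a common library total; SD, n = 3) in homozygous and 4828 ± 1270 in wild-type libraries. Pax7, the satellite cell transcription factor, was at 31.7 ± 18.04 and 76.0 ± 10.4 CPM.

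The series asks how loss of lamin A/C alters transcription in muscle stem cells, with Polycomb repression as its stated interest. Relative to all gene reads, homozygous libraries held less RNA from many genes of satellite cell identity, myogenic commitment, cell division and imprinted growth control, and from fibroblast markers. They held more RNA from lipid-storage genes and from some p53 targets and interferon-responsive genes. Lmna itself (chromosome 3, positions 88480147 to 88509956, minus strand, build GRCm38) was at 421 ± 40.0 CPM in homozygous and 946 ± 108 CPM in wild-type libraries, a log2 fold change of -1.17 (SE 0.14, adjusted p = 0.0010). Each homozygous library lay below each wild-type library. The count covers the whole gene, undeleted exons included, so it checks the labels only in part.

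Of 14099 genes tested, 1363 were higher and 1617 lower in homozygous cells with edgeR's quasi-likelihood test, 2980 in all, and 5056 had an unadjusted p under 0.05. Of these, changes of at least 2-fold were found for 430 of the higher and 715 of the lower genes. Homozygous and wild-type values did not overlap for 99.1% of the called genes and for 40.7% of all genes tested, where 10% is the share given by chance. The number of genes called depended on single libraries, at 1587 without homozygous replicate 1, 1576 without homozygous replicate 3, 1602 without wild-type replicate 1 and 1818 without wild-type replicate 2. A test against a fold change of 1.5 called 533 genes, 199 higher and 334 lower, and with presence of Y-linked reads as a covariate, chosen after seeing the data, 1932 genes were called.

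**Figure D1:**
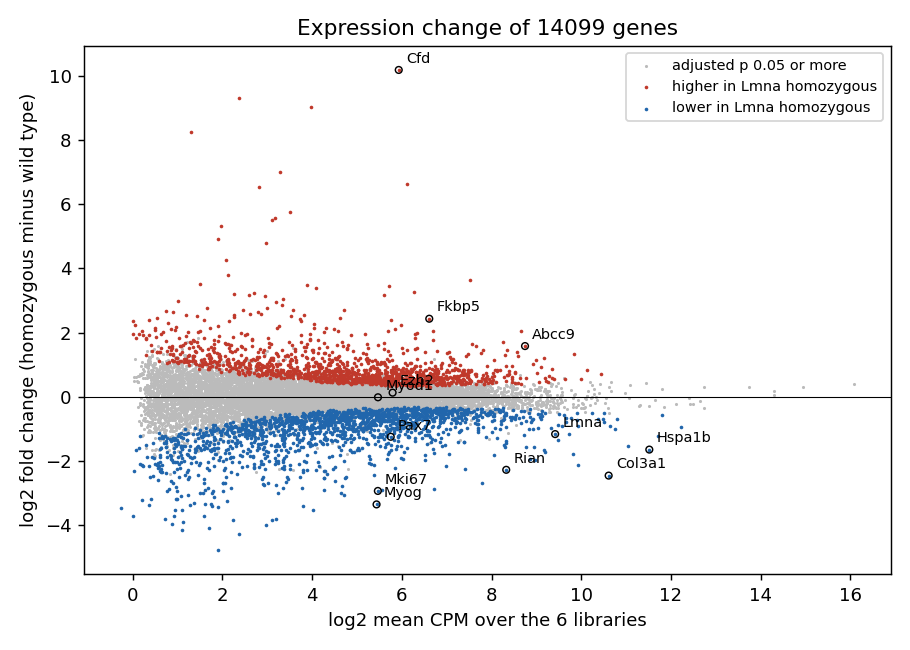
Log2 fold change (homozygous minus wild type, vertical axis) against log2 mean CPM over the 6 libraries (horizontal axis) for 14099 genes, with the 1363 higher genes in red, the 1617 lower genes in blue and all others in grey. Lmna, Pax7, Myog, Mki67, Rian, Col3a1 and Hspa1b lie among the lower genes, Cfd, Fkbp5 and Abcc9 among the higher ones, and Myod1 and Ezh2 near 0.

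Genes of satellite cell identity and quiescence were mostly lower: 15 of 23 measured members fell and 1, Sdc3, rose, or 19 and 1 adjusted over the list alone. None rose without homozygous replicate 2, homozygous replicate 3 or any 1 wild-type replicate. Their median log2 fold change was -0.95, with a camera adjusted p = 4.4e-08 and an adjusted p = 0.465 with an estimated correlation. With fry the list's adjusted p was 0.0885. Col15a1, a collagen of the basement membrane, fell from 383 ± 41.3 to 58.4 ± 37.1 CPM (log2 fold change -2.70, SE 0.37, adjusted p = 0.0015), with a log2 fold change of -3.34 without homozygous replicate 2. Vcam1, an adhesion molecule used to sort satellite cells, had a log2 fold change of -1.80 (SE 0.27, adjusted p = 0.0023), and Cdh15, or M-cadherin, of -2.45 (SE 0.38, adjusted p = 0.0027). Pax7 had a log2 fold change of -1.25 (SE 0.31, adjusted p = 0.0179), and its adjusted p was 0.0677 without homozygous replicate 1, 0.0518 without homozygous replicate 3 and 0.0651 without wild-type replicate 1. Its log2 fold change was -1.84 without homozygous replicate 2. Myf5 did not pass the test, at 51.8 ± 47.2 against 142 ± 6.39 CPM (log2 fold change -1.44, SE 0.46, adjusted p = 0.0512), and passed it without homozygous replicate 2 (adjusted p = 7.5e-07). That library stood at 106 CPM for Myf5 and 52.4 CPM for Pax7, where homozygous replicates 1 and 3 stood at 23.9 and 25.1 CPM for Myf5 and at 23.1 and 19.5 CPM for Pax7. The number of lower members was 7 without homozygous replicate 1, 8 without homozygous replicate 3, 7 without wild-type replicate 1 and 8 without wild-type replicate 2.

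Among genes of myogenic commitment and fusion, 10 of 19 measured members fell and 0 rose, or 12 and 1 adjusted over the list alone (median log2 fold change -1.12, camera adjusted p = 1.5e-05, and adjusted p = 0.465 with an estimated correlation). Without homozygous replicate 2, 1 rose. Myog, the transcription factor of terminal differentiation, was at 7.26 ± 9.79 against 79.2 ± 28.5 CPM (log2 fold change -3.36, SE 0.68, adjusted p = 0.0080, and -5.60 without homozygous replicate 2). Mymk, which encodes the fusion protein myomaker, had a log2 fold change of -3.72 (SE 0.65), on 10 reads in the homozygous and 124 in the wild-type group. Without homozygous replicate 2 the homozygous group held 1 Mymk read, a ratio of 78.7 (95% counting interval 13.9 to 3130) of wild type to homozygous. Chrna1, a subunit of the muscle acetylcholine receptor, had a log2 fold change of -2.64 (SE 0.29). Myod1, the myogenic determination factor, was at 43.9 ± 8.14 CPM in homozygous and 44.5 ± 4.22 CPM in wild-type libraries (log2 fold change -0.02, SE 0.15, adjusted p = 0.939), so no difference was detected for it. Its sign turned without homozygous replicate 3 (0.12) or wild-type replicate 1 (0.05). Of the contractile and fibre genes, 9 of 28 fell and 0 rose, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00064, and adjusted p = 0.465 with an estimated correlation). Among them were Ryr1, the calcium release channel, at -1.85 (SE 0.31), and Actn3, a fast-fibre actinin, at -2.20 (SE 0.39). Without homozygous replicate 2, Actn3 was at -2.98 and 2 contractile genes rose. In the Notch pathway 4 of 18 members fell and 1 rose, the same numbers as adjusted over the list alone (camera adjusted p = 0.156, and 0.0394 without homozygous replicate 2). Nrarp, a Notch target, had a log2 fold change of -0.91 (SE 0.14, adjusted p = 0.0027). A single Notch member was lower without homozygous replicate 1, homozygous replicate 3 or wild-type replicate 1, and 2 were without wild-type replicate 3. None was higher without homozygous replicate 1, homozygous replicate 3 or any 1 wild-type replicate.

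**Figure D2:**
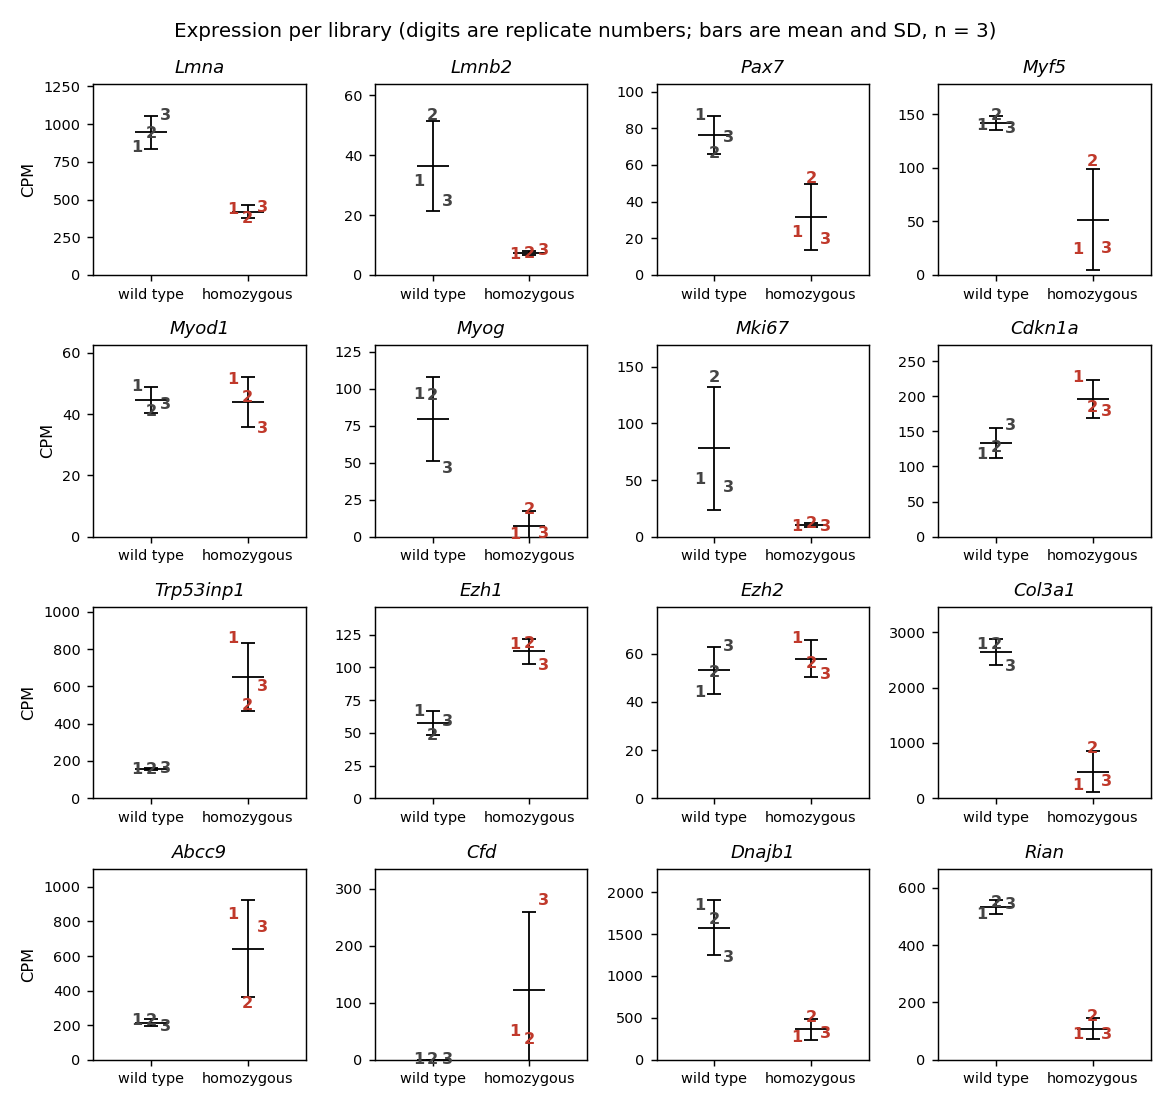
CPM of 16 genes in each library, with the digit giving the replicate number, wild type in grey and homozygous in red, and bars for the mean and SD (n = 3). Homozygous replicate 2 lies nearest the wild-type libraries for Pax7, Myf5, Myog and Col3a1 but not for Lmna, where it is the lowest at 375 CPM, and homozygous replicate 3 is the highest for Cfd.

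Genes of S phase and mitosis were lower for 13 of 28 measured members and higher for 1, or 15 and 3 adjusted over the list alone (median log2 fold change -0.90, camera adjusted p = 0.0061, and adjusted p = 0.720 with an estimated correlation). The list's camera adjusted p was 0.0840 without homozygous replicate 2 and wild-type replicate 2, the libraries high in Gm42418, an alternative chosen after seeing the data. Summed over the list, wild-type replicate 2 stood at 984 CPM, wild-type replicates 1 and 3 at 513 and 531 CPM, and the homozygous libraries at 500.1 to 596 CPM. Mki67, the proliferation marker, was at 10.03 ± 1.69 CPM in homozygous and 78.2 ± 54.4 CPM in wild-type libraries (log2 fold change -2.94, SE 0.42, adjusted p = 0.0019), with 141 CPM in wild-type replicate 2, without which the log2 fold change was -2.22. Cenpf, a kinetochore protein, had a log2 fold change of -4.001 (SE 0.51), and Aurkb, a mitotic kinase, of -4.18 (SE 0.82), on 5 reads in the homozygous and 87 in the wild-type group. Without homozygous replicate 2 the homozygous group held 1 Aurkb read, a ratio of 55.2 (95% counting interval 9.65 to 2210) of wild type to homozygous, and without wild-type replicate 2 the log2 fold change was -3.46. The number of lower members was 6 without homozygous replicate 1, 8 without homozygous replicate 3 and 8 without wild-type replicate 2, and that of higher members was 0 without wild-type replicate 1 or 3, 2 without wild-type replicate 2 and 3 without homozygous replicate 2. Of the replication-dependent histones, 7 of 54 rose and 3 fell, the same numbers as adjusted over the list alone. Their median log2 fold change was -0.23, while the camera test pointed upward (adjusted p = 0.114, and 0.0382 without homozygous replicate 2, 1.7e-08 without wild-type replicate 2 and 0.908, pointing downward, without wild-type replicate 3). Hist1h1c, a linker histone, rose at 1.31 (SE 0.17, adjusted p = 0.0014), and Hist1h3c, a core histone, was lower at -3.53 (SE 0.87, adjusted p = 0.0188), with an adjusted p of 0.0701 without homozygous replicate 1 and a log2 fold change of -1.70 without wild-type replicate 2. The histone split varied with single libraries, at 3 higher and 0 lower without homozygous replicate 1, 4 and 1 without homozygous replicate 3, 3 and 5 without wild-type replicate 1, 20 and 1 without wild-type replicate 2, and 5 and 7 without wild-type replicate 3. Histone genes share near-identical sequence, so the counts of single members are uncertain.

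Cell cycle inhibitors and senescence genes moved in both directions, with 3 of 19 measured members higher and 3 lower, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.978). The split was 2 and 1 without homozygous replicate 1, wild-type replicate 1 or wild-type replicate 2, and 5 and 3 without homozygous replicate 2. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was at 196 ± 26.9 against 134 ± 21.6 CPM (log2 fold change 0.55, SE 0.15, adjusted p = 0.0264). Its adjusted p was 0.0947 without homozygous replicate 1, 0.113 without wild-type replicate 1 and 0.0823 without wild-type replicate 2. Igfbp5, an insulin-like growth factor binding protein, had a log2 fold change of -1.98 (SE 0.20, adjusted p = 0.00058). Cdkn2a, the locus of p16 and p19 known as a Polycomb target, had 3 reads over the 6 libraries, with 1 in the homozygous and 2 in the wild-type group. At this depth 3 reads over a group correspond to 0.124 CPM in homozygous and 0.131 CPM in wild-type libraries. Both groups lay under that level, so counted Cdkn2a RNA was low in both genotypes. A difference between levels this low was not detectable. Of the p53 targets, 7 of 20 rose and 0 fell, also when adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.0071, and adjusted p = 0.465 with an estimated correlation). Without homozygous replicate 1 the number was 4. Trp53inp1, a stress-induced partner of p53, was at 651 ± 184 against 156 ± 4.10 CPM (log2 fold change 2.06, SE 0.19, adjusted p = 0.00045). Sesn1, a sestrin, rose at 0.98 (SE 0.14) and Ccng1, or cyclin G1, at 0.84 (SE 0.13).

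In the nuclear lamina and envelope list, 5 of 21 members rose and 4 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.978). Besides Lmna, Lmnb2, which encodes lamin B2, was at 7.48 ± 0.67 against 36.3 ± 15.1 CPM (log2 fold change -2.27, SE 0.27, adjusted p = 0.00095). Sun2, a protein of the inner nuclear membrane that links to the cytoskeleton, rose from 194 ± 9.33 to 343 ± 18.3 CPM (log2 fold change 0.82, SE 0.12, adjusted p = 0.0017). Tmem43, another inner membrane protein, had the same log2 fold change of 0.82 (SE 0.12). In each fit without homozygous replicate 1, homozygous replicate 3 or any 1 wild-type replicate, 3 members were higher.

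Polycomb complex members were higher for 5 of 32 and lower for 1, Jarid2, the same numbers as adjusted over the list alone (median log2 fold change 0.05, camera adjusted p = 0.146). Without homozygous replicate 1, 3 were higher, and 3 were lower without homozygous replicate 2 but 0 without any other replicate. Ezh1, a histone H3 lysine methyltransferase of Polycomb repressive complexes, was at 112 ± 9.64 against 57.9 ± 9.14 CPM (log2 fold change 0.95, SE 0.14, adjusted p = 0.0019). Cbx7, a chromodomain subunit, had a log2 fold change of 1.18 (SE 0.18, adjusted p = 0.0025). Ezh2, the paralogue of Ezh1, was at 57.8 ± 7.63 against 53.1 ± 9.70 CPM (log2 fold change 0.12, SE 0.15, adjusted p = 0.598). Classical Polycomb-bound developmental regulators were mostly too low to test: 19 of 66 were measured, of which 0 rose and 3 fell, also when adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 0.134). They included the developmental transcription factors Tbx15 and Zic1, of which Tbx15 had a log2 fold change of -0.75 (SE 0.13, adjusted p = 0.0041). The adjusted p of Zic1 was 0.0155, and 0.0647 without wild-type replicate 1. The number of lower regulators was 6 without homozygous replicate 2 and 1 without wild-type replicate 1. The 47 untested members held 180 reads in the homozygous and 219 in the wild-type group. Of the Hox genes, 19 of 39 were measured, of which 0 rose and 2 fell, Hoxc10 and Hoxa9, and 0 passed when adjusted over the list alone (camera adjusted p = 0.124). Neither Hox gene passed without homozygous replicate 1, homozygous replicate 3 or wild-type replicate 1, 1 Hox gene did without wild-type replicate 2 or 3, and 4 did without homozygous replicate 2. The 20 untested Hox genes held 197 reads in the homozygous and 214 in the wild-type group.

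Imprinted growth genes were lower for 13 of 20 measured members and higher for 0, or 14 and 1 adjusted over the list alone (median log2 fold change -0.93, camera adjusted p = 4.4e-08, and adjusted p = 0.465 with an estimated correlation). 1 rose without homozygous replicate 2 or wild-type replicate 3. Rian, a maternally expressed noncoding RNA of the Dlk1-Meg3 region, was at 109 ± 35.6 against 533 ± 22.8 CPM (log2 fold change -2.28, SE 0.21, adjusted p = 0.00042). Dlk1, a paternally expressed Notch-like protein, had a log2 fold change of -2.997 (SE 0.25), Mirg, the microRNA host of that region, of -2.002 (SE 0.17), and Mest of -1.77 (SE 0.14). H19 and Igf2 fell as well, at -1.48 (SE 0.21) and -1.10 (SE 0.16). Rian and Mirg overlap small RNA genes and Mest overlaps Copg2 on the other strand. The strand setting of the counting is not given in the sources used here, so reads of such overlapping genes may be shared.

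Lipid-storage genes were mostly higher. In the adipogenic list 11 of 16 measured members rose and 1, Ppargc1a, fell, the same numbers as adjusted over the list alone (median log2 fold change 0.99, camera adjusted p = 0.00012, and adjusted p = 0.465 with an estimated correlation). With fry the list's adjusted p was 0.0717. Ppargc1a, a coactivator of mitochondrial genes, was called in the fits without homozygous replicate 2 or wild-type replicate 2 and in no other that left out a replicate. Cfd, the secreted protease adipsin, had 2832 reads in the homozygous and 2 in the wild-type group, a ratio of 1350 after scaling by library totals (95% counting interval 373 to 11100), and of 473 without homozygous replicate 3. Cidec, a lipid droplet protein, had 728 and 1, a ratio of 693 (124 to 27400). That of Cidec was 318 without homozygous replicate 3 and 439 without wild-type replicate 1, and it was at least 151-fold higher without wild-type replicate 3, which held the 1 read. Outside the list, Apoc3, an apolipoprotein, had 236 reads in the homozygous and 0 in the wild-type group, at least 74.9-fold higher, and Adig, or adipogenin, had 115 and 0, at least 36.5-fold higher, each against 3 reads over the group. Without homozygous replicate 3, wild-type replicate 1 and wild-type replicate 3 in turn, the bound was 38.1, 47.4 and 49 for Apoc3 and 21.3, 23.1 and 23.9 for Adig. The bound for Apoc3 was 116 without homozygous replicate 2. The 3 untested adipogenic genes held 103 reads in the homozygous and 6 in the wild-type group. Counting intervals and floors cover counting error only. Cfd stood at 49.5, 36.3 and 280 CPM in homozygous replicates 1, 2 and 3. Among genes with clear expression in wild type, Pnpla2, the lipase that opens triglyceride breakdown, had a log2 fold change of 1.36 (SE 0.14, adjusted p = 0.00058) and Plin4, a lipid droplet coat protein, of 1.44 (SE 0.15, adjusted p = 0.00062). Hp, or haptoglobin, was at 138 ± 139 against 1.35 ± 0.48 CPM (log2 fold change 6.64, SE 1.03, adjusted p = 0.0027, and 5.49 without homozygous replicate 3).

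Markers of other cell types moved apart from each other. Fibro-adipogenic progenitor and fibroblast markers were lower for 11 of 14 members and higher for 1, Pdgfra, or 12 and 1 adjusted over the list alone (median log2 fold change -1.23, camera adjusted p = 8.3e-06, and adjusted p = 0.465 with an estimated correlation). None was higher without homozygous replicate 1, wild-type replicate 1 or wild-type replicate 2. Col3a1, a fibrillar collagen, was at 479 ± 369 against 2647 ± 236 CPM (log2 fold change -2.47, SE 0.43, adjusted p = 0.0046, and -3.31 without homozygous replicate 2). Smoc2, a matrix protein, had a log2 fold change of -1.35 (SE 0.13). Tenocyte markers were lower for 3 of 8 members and higher for 0, also when adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.518 with an estimated correlation). Kera, or keratocan, had a log2 fold change of -4.79 (SE 0.61), on 6 reads in the homozygous and 162 in the wild-type group. The 6 reads lay in homozygous replicate 2, without which Kera was at least 34.3-fold lower, against 3 reads over the group. The number of lower tenocyte markers was 6 without homozygous replicate 2 and 1 without any other replicate. Erythroid genes were lower for 4 of 7 members and higher for 0, or 7 and 0 adjusted over the list alone (median log2 fold change -1.67, camera adjusted p = 0.00029, and adjusted p = 0.465 with an estimated correlation). Their number was 7 without homozygous replicate 2, 1 without homozygous replicate 1 or homozygous replicate 3, and 0 without wild-type replicate 2 or wild-type replicate 3. The haemoglobin genes among them have near-identical copies.

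Pericyte and smooth muscle markers were higher for 4 of 11 members and lower for 1, Myh11, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.146). The number lower was 2 without homozygous replicate 2 and 0 without homozygous replicates 1 or 3 or wild-type replicates 1 or 2. Abcc9 and Kcnj8, subunits of the potassium channel of pericytes, rose at 1.58 (SE 0.29) and 1.38 (SE 0.28), and Pdgfrb, a receptor of mural cells, rose at 1.02 (SE 0.17, adjusted p = 0.0036). Schwann and glial markers were higher for 3 of 11 members and lower for 4, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.534). S100b, a calcium-binding protein, was lower at -1.33 (SE 0.25). Their split was 2 and 1 without homozygous replicate 1, 1 and 2 without homozygous replicate 3, 1 and 1 without wild-type replicate 1, 1 and 2 without wild-type replicate 2, and 3 and 1 without wild-type replicate 3. Of the endothelial markers, 1 of 14 rose, Fabp4, and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.978). Fabp4 is a fatty acid carrier also known from adipocytes, and its adjusted p of 0.0173 became 0.0577 without homozygous replicate 3, 0.0627 without wild-type replicate 2 and 0.0532 without wild-type replicate 3. The endothelial list had 5 lower members without homozygous replicate 2. Of the macrophage and monocyte markers, 2 of 10 rose, Cd68 and Cd14, and 0 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.682). 1, Cd68, was higher without homozygous replicate 1, homozygous replicate 3 or any 1 wild-type replicate, and 2 macrophage markers were lower without homozygous replicate 2 and 1 without wild-type replicate 2. Of 7 neutrophil markers 0 passed, also when adjusted over the list alone (camera adjusted p = 0.359), and without homozygous replicate 3 the number lower was 2 and the list's camera adjusted p 0.0073. The only measured lymphoid marker of 11, Lck, was at 1.44 ± 0.04 against 1.56 ± 0.70 CPM (adjusted p = 0.820). The 10 untested lymphoid markers held 82 reads in the homozygous and 282 in the wild-type group, 64 of them in homozygous replicate 2 and 176 in wild-type replicate 3. Of 4 lymphoid markers measured without homozygous replicate 2 or wild-type replicate 2, 2 and 1 were lower.

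**Figure D3:**
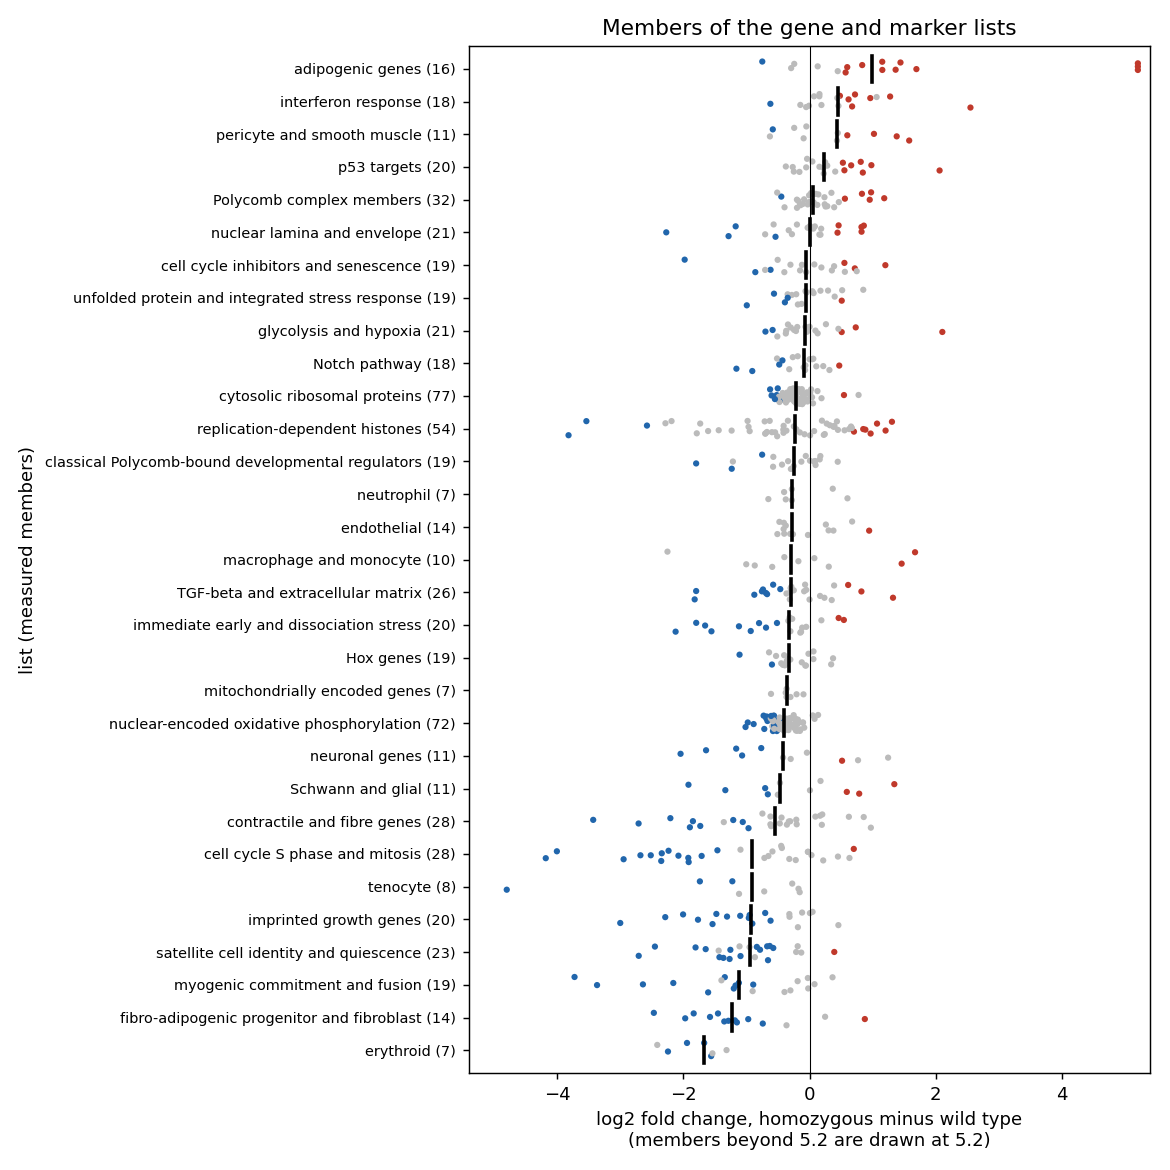
Log2 fold change (homozygous minus wild type, horizontal axis) of each measured member of the 31 gene and marker lists with at least 5 measured members (vertical axis, number measured in parentheses), with higher genes in red, lower genes in blue, genes that did not pass in grey and a bar at each list's median. Members beyond 5.2 are drawn at 5.2, and the medians run from -1.67 for erythroid to 0.99 for adipogenic genes.

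Immediate early and dissociation stress genes were lower for 9 of 20 members and higher for 2, also when adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 0.00037, and adjusted p = 0.465 with an estimated correlation). The number higher was 0 without homozygous replicate 3 or wild-type replicate 1 and 1 without homozygous replicate 1 or wild-type replicate 3. Those with the smallest p were Dnajb1 and Hsph1, heat shock co-chaperones, at -2.12 (SE 0.25, adjusted p = 0.00091) and -1.79 (SE 0.28, adjusted p = 0.0029), and the immediate early transcription factors Egr2, at -1.12 (SE 0.18), and Nr4a1, at -0.80 (SE 0.14). Interferon-responsive genes were higher for 7 of 18 members and lower for 1, Cxcl10, or 8 and 1 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.0103, and adjusted p = 0.547 with an estimated correlation). Isg15, a ubiquitin-like protein, was at 14.8 ± 2.20 against 6.08 ± 0.29 CPM (log2 fold change 1.28, SE 0.19, adjusted p = 0.0022). 3 were higher without homozygous replicate 1, homozygous replicate 3, wild-type replicate 1 or wild-type replicate 2, and the list's camera adjusted p was 0.0622 without wild-type replicate 2. In the list of TGF-beta signalling and extracellular matrix 9 of 26 members fell and 3 rose, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0562). Lox, a collagen cross-linking enzyme, rose at 0.82 (SE 0.14) and Tgfb2 was lower at -0.74 (SE 0.13). 4 were lower without homozygous replicate 1 or homozygous replicate 3, and the camera adjusted p was 0.0147 without homozygous replicate 2 and 0.0337 without wild-type replicate 2.

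Of the nuclear-encoded genes of oxidative phosphorylation, 19 of 72 fell and 0 rose, or 32 and 0 adjusted over the list alone (median log2 fold change -0.41, camera adjusted p = 4.4e-08, and adjusted p = 0.603 with an estimated correlation). Ndufc2, of complex I, had a log2 fold change of -0.98 (SE 0.20) and Uqcrb, of complex III, of -0.68 (SE 0.13, adjusted p = 0.0064). The number was 5 without homozygous replicate 1, 7 without homozygous replicate 3, 11 without wild-type replicate 1, 8 without wild-type replicate 2 and 29 without wild-type replicate 3. Of the 7 measured mitochondrially encoded genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.0359, and adjusted p = 0.558 with an estimated correlation), with mt-Co1 at 5998 ± 379 against 7708 ± 652 CPM. 1 was lower without homozygous replicate 2. The list's camera adjusted p was 0.159 without homozygous replicate 3, 0.0534 without wild-type replicate 2 and 0.0743 without wild-type replicate 3. Cytosolic ribosomal protein genes were lower for 6 of 77 members and higher for 1, and 0 passed when adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.00036, and adjusted p = 0.769 with an estimated correlation). A single ribosomal protein gene was lower without homozygous replicate 1, wild-type replicate 2 or wild-type replicate 3, 0 were without homozygous replicate 3, and the list's camera adjusted p was 0.124 without wild-type replicate 2. None was higher without homozygous replicate 1, homozygous replicate 3, wild-type replicate 1 or wild-type replicate 3. In the glycolysis and hypoxia list 3 of 21 members rose and 2 fell, or 3 and 3 adjusted over the list alone, with 1 lower without homozygous replicates 1 or 3 or wild-type replicates 1 or 2 (camera adjusted p = 0.682). The smallest p was that of Bnip3, a hypoxia-induced mitophagy receptor, at 93.2 ± 39.1 against 21.6 ± 3.58 CPM (log2 fold change 2.10, SE 0.29, adjusted p = 0.0016). In the list of the unfolded protein and integrated stress response 4 of 19 members fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.359). Psat1, a serine synthesis enzyme, had a log2 fold change of -0.99 (SE 0.17, adjusted p = 0.0041). 1 member was lower without homozygous replicate 1, homozygous replicate 3 or any 1 wild-type replicate, and 2 were lower and 4 higher without homozygous replicate 2. No member of that list was higher without homozygous replicate 1, homozygous replicate 3, wild-type replicate 1 or wild-type replicate 2. Neuronal genes were lower for 5 of 11 members and higher for 1, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.146). Map2, a microtubule-associated protein, had a log2 fold change of -0.76 (SE 0.14). The number of lower members was 1 without homozygous replicate 1, 2 without homozygous replicate 3 or wild-type replicate 3, and 3 without wild-type replicate 1 or wild-type replicate 2. No neuronal gene was higher without homozygous replicate 1, wild-type replicate 1 or wild-type replicate 3.

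Of the shares of counts compared between genotypes, 4 separated all homozygous from all wild-type libraries, at the smallest exact two-sided permutation p that 3 against 3 can give, 0.1. Rn7sk, an abundant small nuclear RNA, took 7.85 ± 0.709% of gene counts in homozygous and 5.92 ± 0.602% in wild-type libraries. Mitochondrially encoded protein-coding genes took 0.742 ± 0.036% and 0.932 ± 0.040% of gene counts, and 0.930 ± 0.040% and 1.12 ± 0.072% of protein-coding counts. The 10 most abundant protein-coding genes took 5.64 ± 0.343% and 6.45 ± 0.351% of protein-coding counts. Other shares overlapped between genotypes. All mitochondrially encoded genes together took 4.54 ± 1.05% of gene counts in homozygous and 3.97 ± 0.55% in wild-type libraries (exact permutation p = 0.6). The 10 most abundant genes took 20.3 ± 1.77% and 17.4 ± 1.54% (exact permutation p = 0.2), and histone genes 0.196 ± 0.025% and 0.157 ± 0.095% (exact permutation p = 0.5). Reads assigned to no gene were 47.9 ± 2.55% and 46.6 ± 1.54% of all reads in the files (exact permutation p = 0.5). With adjustment over the 14 quantities compared, the smallest adjusted p was 0.35, and no value could have passed the threshold in this design. Gm42418, a predicted gene known to overlap ribosomal RNA sequence, stood at 13030 CPM in homozygous replicate 2 and 13900 CPM in wild-type replicate 2, against 914 to 1797 CPM in the other libraries. Without those libraries, an alternative chosen after seeing the data, 1695 genes were higher and 2163 lower.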

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

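The Y-linked covariate and the omission of the Gm42418-high libraries were chosen after seeing the data. No called gene had the opposite sign under any alternative. DESeq2 size factors, library totals, the DESeq2 test (9714 genes with no adjusted p), voom weights, other filters, thinning and omission of gene families gave 2710 to 4104 called genes against 2980. A test against a fold change of 1.5 called 533 (199 higher, 334 lower), fewer by construction. Leaving out a library gave 1576 to 4002 genes, 655 to 1764 of them higher and 881 to 2238 lower, on fewer samples. With Y-linked reads as a covariate 1932 were called, 793 of them higher. With a replicate block 2437 genes and 15 lists were called. Deviations of same-numbered libraries correlated at -0.036, 0.022 and -0.096, which gave no sign of pairing. With 3 libraries per genotype this cannot exclude a step shared by number, and the 2 libraries high in Gm42418 were both numbered 2. Of the lists, 15 passed in camera with the preset correlation, 0 with an estimated correlation (0 higher, 0 lower) and 4 with fry (1 higher, 3 lower). By fry adjusted p these were p53 targets (0.0370, higher), imprinted growth (0.0370), immediate early and dissociation stress (0.0389) and fibroblast markers (0.0403). The lowest fry adjusted p among the remaining lists was 0.0717, with S phase and mitosis at 0.349 and nuclear-encoded oxidative phosphorylation at 0.202. Without the Gm42418-high libraries 5 lists were higher, against 3, with histones (8.57e-10) and pericyte (0.0235) added. Notch (0.0204), Polycomb-bound regulators (0.0496), TGF-beta and matrix (0.00912) and endothelial (0.0157) were added to the lower lists, and S phase and mitosis was lost (0.0840, with 1.41e-05 to 0.720 over its alternatives). Some uncalled genes turned sign. Myod1 turned to 0.024 when thinned and ran from -0.14 to 0.12 as libraries were left out, and Lck turned to 0.13 when thinned and ran from -0.42 to 0.14. S100a8 ran from -1.51 to 0.15, S100a9 from -1.22 to 0.14 and Ezh2 from -0.0049 to 0.27. S100a8 and S100a9 passed the test without homozygous replicate 3 (edgeR adjusted p = 0.0161 and 0.0285). Uncalled lists also turned. As libraries were left out, adjusted p ran from 0.638 to 0.940 for inhibitors and senescence, 0.186 to 0.976 for endothelial, 0.287 to 0.872 for macrophage, 0.00726 to 0.692 for neutrophil, 0.869 to 0.995 for lamina and 1.72e-08 to 0.908 for histones. Inhibitors and senescence also turned with fry (0.914) and the Y covariate (0.941), and endothelial with the replicate block (0.993) and the Y covariate (0.971). Without the Gm42418-high libraries lamina (0.997) and unfolded protein response (0.950) turned. Over protein-coding genes alone, the difference in mitochondrial share turned from 0.568 to -0.191 percentage points and that of the 10 most abundant genes from 2.97 to -0.807. Both protein-coding shares separated the genotypes without overlap, at the smallest possible exact permutation p of 0.1. The mitochondrial turn came from leaving out noncoding mitochondrial genes, since the protein-coding ones also differed by -0.191 points as a share of all gene counts. The 2 shares of the 10 most abundant genes cover different genes, and noncoding Rn7sk alone differed by 1.92 points of gene counts. The cause of the other turns was not tested. Depth limits what can be said of Cdkn2a and of the untested 47 Polycomb-bound regulators and 20 Hox genes.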

Other observations

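The groups in this paragraph and the next were put together after seeing the data, so their counts describe these libraries and are not independent evidence. Heat shock chaperones fell almost throughout, with 22 of 23 members lower, 0 higher and Hspb8 not called (median log2 fold change -1.09). Hsp90aa1, an abundant cytosolic chaperone, was at 1996 ± 397 CPM (SD, n = 3) in homozygous and 4706 ± 181 CPM in wild-type libraries (log2 fold change -1.24, SE 0.18, adjusted p = 0.0019), and Hspd1, the mitochondrial chaperonin, at 276 ± 77.1 against 878 ± 41.9 CPM (log2 fold change -1.67, SE 0.19). Hspa1a and Hspa1b, near-identical copies, were both lower. Of 22 measured genes of cholesterol synthesis, 16 fell and 0 rose (median log2 fold change -0.76), among them Hmgcs1, at 259 ± 8.43 against 589 ± 141 CPM. Of 11 myelin genes, 3 fell, 0 rose and 8 were not called. Of 10 genes of non-myelinating Schwann cells and glia, 5 rose and 2 fell, with Scn7a, a sodium channel of non-myelinating cells, at 419 ± 112 against 216 ± 48.0 CPM (adjusted p = 0.0136). The difference between the subsets was not tested.

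Some genes known to respond to glucocorticoids, the adrenal stress hormones, were among the clearest increases. Of 16 seen in the data, 11 were higher and 0 lower. The other 5, Sgk1, Klf9, Pdk4, Angptl4 and Errfi1, were not called. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 165 ± 47.8 against 30.5 ± 8.14 CPM (log2 fold change 2.43, SE 0.25, adjusted p = 0.00058), and Klf15 at 91.6 ± 15.4 against 17.3 ± 1.29 CPM (log2 fold change 2.40, SE 0.15, adjusted p = 0.00021). Tsc22d3, or GILZ, and Zbtb16 also rose, at 1.152 (SE 0.14) and 1.76 (SE 0.15). A hypothesis is that homozygous animals were under more glucocorticoid action. It was tested on 9 further responsive genes not looked at before, of which 4 were higher, or 44.4% (exact 95% interval 13.7 to 78.8%), and 1 lower, against 9.67% of all genes higher. The rule set before needed most of the 9 to be higher and counted a minority against the hypothesis. With 4 of 9, a minority, the result went against the hypothesis by that rule. The interval, which was not part of the rule, covers both minority and majority shares. By the interval, 9 genes are too few to decide and the hypothesis stays open.

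Of the tests below, those of mixing into homozygous replicate 2, of adipocyte RNA, of dilution by other cell types and of satellite genes without Myod1 were chosen after the results were seen. Those of sex, of all satellite-restricted genes and of other splits were set before. The satellite-restricted set itself is not among the lists fixed before the data were examined.

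Homozygous replicate 2 lay between the genotypes: over 1610 genes called without it and changed at least 2-fold, its median position was 0.387, where 0 is the mean of the other homozygous libraries and 1 that of wild type. The position was 0.544 for the higher and 0.322 for the lower genes, and ran from 0.0763 for S phase and mitosis to 0.811 for pericyte markers over the lists. These genes were selected on the other libraries, which can itself draw a held-out library towards wild type, and no other library was placed this way. Over all genes tested, homozygous replicate 2 correlated at 0.968 and 0.972 with homozygous replicates 1 and 3, and at 0.954 to 0.969 with wild-type libraries. Wild-type cells or RNA mixed in at the share the overall median gives would move Lmna as well, but Lmna lay at -0.136, with 375 CPM where that median predicts 638 (wild-type SD 108), which argues against mixing at that share. A sex effect common to both genotypes could not be tested well: the library's difference from the other homozygous libraries correlated across genes at -0.116 with the difference between wild-type libraries with and without Y-linked reads, but 1 library on each side of that comparison stands alone with its own deviation. A sex effect, common or in mutants alone, or a milder state of the sample may therefore remain. Homozygous replicate 2 was also high in Gm42418, at 13030 CPM, as was wild-type replicate 2, at 13900 CPM. Whether this goes with the position of homozygous replicate 2 was not tested.

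Of 12 genes listed as adipocyte-restricted 8 were measured and 7 were higher, with Cfd, the most abundant, at 49.5, 36.3 and 280 CPM in homozygous replicates 1, 2 and 3, while Thrsp was not called (2.81 ± 1.11 against 3.73 ± 1.14 CPM). Adipoq, or adiponectin, was at 17.6 ± 17.0 against 0.35 ± 0.14 CPM, but Cdo1 and Trarg1 were present in wild type at 8.88 ± 0.775 and 8.54 ± 1.37 CPM. Adipocytes or their free RNA could bring these transcripts, although the sort for satellite cells should remove adipocytes, and 6 of 7 called genes, 85.7%, shared the order replicate 3, 1, 2. Among the 8 measured genes, Car3 and the uncalled Thrsp did not share that order. That order was taken from these libraries and a change within the sorted cells could share it, so the 2 cannot be told apart. The same holds for 7 lipid genes with at least 10 CPM in wild type, whose median ratio of the excess in homozygous replicate 3 to that in replicate 2 was 1.84, against 5.94 for the adipocyte-restricted genes, with overlapping ranges (0.749 to 15.6 and 2 to 9.65).

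Satellite cell genes were lower together, which a lower share of satellite cells in the homozygous sort could give. A lower share alone would give all satellite-restricted genes a common fold change, and 10 such genes differed among themselves (Cochran's heterogeneity test, p = 5.6e-09), which rests on Myod1, whose ratio to Pax7 was 1.63 ± 0.696 in homozygous and 0.588 ± 0.028 in wild-type libraries (exact permutation p = 0.1, the smallest possible with 3 against 3). Without Myod1 the same statistic on edgeR estimates was 11.1. The heterogeneity test takes genes as independent, but these come from the same libraries. Homozygous replicate 2 was the highest homozygous library for each of the other 9 genes. Both p-values of the heterogeneity test therefore lack their nominal meaning. A lower share and lower expression per cell cannot be told apart for the other 9 genes, since genotype and share go together here. Dilution by all other cell types alike would raise their markers together, but the medians of the fibroblast, tenocyte, endothelial and pericyte lists spanned 1.67 on the log2 scale, which argues against it. A change in single other cell types stays open.

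The 6 libraries can be divided 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 2980 genes and the highest other split 5, and 1 of the 10 splits gave as many genes as the real one, itself. For lists tested by camera with the preset correlation, the real split gave 15 and the highest other 18. 3 of the 10 splits gave as many, the real one included. The other 2 put homozygous replicate 2 with wild-type libraries, as did a split that gave 12. Every other split gave at least 6 lists, so the number of lists called does not by itself speak for genotype.

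At the low end, 122 genes had 0 reads in each wild-type library and reads in each homozygous library, and 90 the reverse. Among called genes, 27 were higher from under 0.5 CPM in wild type and 43 lower to under 0.5 CPM in homozygous libraries.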
